A study of Mus musculus with 2 samples.

How the data were processed

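Polyadenylated RNA longer than 200 nt was sequenced as stranded paired-end reads of 76 nt from 2 lung libraries with synthetic spike-ins added, per the labels. Both belong to 1 group, and their replicate numbers are those of the labels. The labels give both libraries the same donor record and separate tissue samples, and do not give the number of animals, so the spread between the libraries may be technical in part.

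The deposited expected counts per gene and transcript are estimated fragment numbers, not normalized, per the file headers. The deposited TPM values are scaled to a fixed total per library over all rows, spike-ins included, and the deposited FPKM values are scaled by length and library total, per the file headers. The percent of a gene's TPM on each transcript is the authors' value, as are the bounds of an interval on the TPM scale whose level is not given in the sources used here. Reads were aligned to mm10 and quantified with GENCODE release M4, per the deposited file lists; the aligner, the quantifier and their versions are not given in the sources used here. The deposited contig list gives a signal level and a reproducibility score per contig, and the deposited junction list gives read counts and a reproducibility score, both on mm9. How these scores were computed is not given in the sources used here. They are the authors' values and were used only to filter within a list. The junction list holds tallies for a pair of libraries that no label ties to a replicate, so only their sum was used.

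Gene symbols came from a later GENCODE release on the same build; 42462 of 43346 gene identifiers matched, and these held 99.9% of counts in each library. The 26249 rows with neither a gene nor a spike-in identifier held 0 and 2 counts and were left out. Expected counts were rounded for edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3; other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Log2 ratios are replicate 2 over replicate 1 of CPM values computed from the counts with TMM scaling and a prior count of 2. A gene was detected at 1 TPM or more in both libraries. A 2-fold difference needed a mean rounded count of at least 50, except within lists. Lists, with their members called 2-fold, and the replicate SD used genes with a mean count of at least 10. The replicate SD is the scaled median absolute deviation of the log2 ratio divided by the square root of 2. The biological coefficient of variation is the square root of edgeR's common dispersion under a design with an intercept only. It was estimated without gene-wise dispersions, because that step failed on the table without a count filter. Folds are ratios of counts over TMM-scaled library sizes with an exact Clopper-Pearson 95% interval, and a count of 0 was read as allowing 3 counts per library.

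The 41 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule for names took the 20 nuclear genes of highest mean TPM, members of the lists, the 12 largest log2 ratios in each direction and a fixed set of genes for their transcripts. The mitochondrial genes and the members of added lists that are named fall outside this rule and were chosen after their values were seen. The level of a list is the median log2(TPM + 1) of its members, ranked among 10000 random lists of genes at 0.1 TPM or more in either library. The difference of a list is the median log2 ratio of members with a mean count of at least 10, for at least 3 members, ranked among 10000 random lists matched in 20 expression bins. Lists of other organs were added after the data were seen; apart from single genes and a plot, they enter only the closing section.

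The scripts were tested on a simulated pair of libraries over 43346 genes with the real means and library sizes. A simulated coefficient of variation of 0.2 was recovered as 0.213. Of 100 genes changed 4-fold, 98 were called with the right direction; of 100 changed 1.5-fold, 14 were called. Of 14514 unchanged genes, 285 were called 2-fold. All 100 shifted lists and 4 of 100 unshifted lists fell outside the central 95% of random lists.

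Alternatives covered other detection thresholds, FPKM, shares of counts, pseudocounts, count minimums, DESeq2 and library size scaling, the deposited TPM intervals, a stricter reproducibility value and leaving out either replicate. The 2-fold count, the correlation and the list differences need both libraries and were not run without one. No test across replicates was possible with 1 group.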

Results

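Polyadenylated RNA of adult mouse lung was sequenced from 2 libraries, each from tissue of C57BL/6J littermates at 8 weeks of age. The labels name both sexes for each library; Xist had 17 and 8 counts. The labels call the libraries biological replicates of 1 group, so no between-group comparison exists and no p-value is given. Levels are the mean ± SD of n = 2 libraries or the values of replicates 1 and 2 in that order, and every difference compares these libraries only. Expected counts on gene rows summed to 48234745 in replicate 1 and 44182836 in replicate 2. Coordinates of genes are on mm10, from a later release of the gene annotation than the one used for quantification.

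The adult lung transcriptome was led by secretory products of the airway and the alveolus. Scgb1a1, the secretoglobin of club cells (chromosome 19, 9083636 to 9087958), stood at 127701 ± 6852 TPM and took 12.8% ± 0.685 of all TPM. Sftpc, which encodes surfactant protein C (chromosome 14, 70520949 to 70524081), followed at 22569 ± 336 TPM. Sftpb, the surfactant protein B gene, reached 5871 ± 1312 TPM, and the carbonyl reductase gene Cbr2 reached 12723 ± 138 TPM. Cyp2f2, a cytochrome P450 of club cells, stood at 3708 ± 130 TPM. The lysozyme gene Lyz2 had 4131 ± 421 TPM, and Mgp, which encodes matrix Gla protein, had 3988 ± 1629 TPM. Igfbp7 was at 3334 ± 1564 TPM, the ferritin heavy chain gene Fth1 at 3724 ± 746 TPM and Actb at 5445 ± 292 TPM. Haemoglobin genes stood high but varied, with Hba-a2 (chromosome 11, 32296489 to 32297298) at 17898 ± 11365 TPM and Hbb-bs (chromosome 7, 103826534 to 103828096) at 12235 ± 7560 TPM. The structured small RNA Rn7sk had 21427 ± 1958 TPM, and the ribosomal protein genes Rplp1 and Rps12 had 6294 ± 1264 and 3041 ± 354 TPM. Rn7s1 and Rn7s2 carried identical counts, 22020 in replicate 1 and 23144 in replicate 2, so their separate levels are uncertain. Gm42418, whose counts were tallied here as those of a ribosomal RNA gene, had 10148 ± 5347 TPM. It held 1.69% of gene counts in replicate 1 against 0.824% in replicate 2.

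A total of 13855 genes reached 1 TPM in both libraries, of which 12986 were annotated as protein coding. A further 998 genes passed in replicate 1 only and 283 in replicate 2 only. The 10 genes highest by TPM in each library held 25.4% ± 2.76 of TPM. The 10 genes highest by expected count in each library, a different set, held 8.92% ± 0.00135 of expected counts. Mitochondrially encoded genes held 3.18% of TPM in replicate 1 and 1.53% in replicate 2, led by mt-Atp8, mt-Co1 and mt-Co3. Of expected counts on gene rows they held 1.58% and 0.840%. Both shares cover only genes with an mt- symbol. Reads assigned to pseudogenes on nuclear chromosomes, such as Gm29216 on chromosome 1 (8103 and 5287 TPM), were counted as nuclear. The TPM of mt-Atp8 rested on 1518 and 488 counts over a short transcript. By contrast, mt-Co1 had 384259 counts in replicate 1 and 188324 in replicate 2.

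Markers of the alveolar epithelium and the pulmonary vasculature were expressed at high levels in both libraries. The alveolar type 2 list had a median of 8.57 ± 0.02 on the log2(TPM + 1) scale, with all 11 members above 1 TPM in both libraries. The alveolar type 1 list, all 10 members detected, had a median of 8.59 ± 0.40, led by Ager (1703 and 1669 TPM in replicates 1 and 2) and Clic3 (1637 and 1491 TPM). Endothelial genes had a median of 7.74 ± 0.03 over 14 members, among them Egfl7 (1797 TPM in both libraries), Cldn5 (669 and 815 TPM) and Cdh5 (501 and 479 TPM). Each of these lists lay at percentile 100 of 10000 random lists of equal size. Club and secretory genes had a median of 8.70 ± 0.94. Ciliated cell genes had a median of 3.39 ± 0.27, with Tppp3 (723 and 731 TPM) and Sec14l3 (650 and 527 TPM) highest and the axonemal dynein gene Dnah5 at 2.09 and 1.59 TPM. The ciliated list lay at the 71.5 percentile of random lists.

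Stromal and matrix genes were also prominent. Fibroblast genes had a median of 6.78 ± 0.23, with Inmt at 1431 and 1476 TPM and Mfap4 at 1171 and 1204 TPM. The extracellular matrix list had a median of 7.57 ± 0.00327, led by Mgp (2836 and 5140 TPM) and Sparc (3247 and 2780 TPM). Smooth muscle genes had a median of 6.30 ± 0.23, pericyte genes 6.08 ± 0.09 and mesothelial genes 5.39 ± 0.28. Lung transcription factors had a median of 6.75 ± 0.28, with Nkx2-1 at 236 and 372 TPM and Foxf1 at 172 and 378 TPM. Xenobiotic metabolism genes stood at 6.86 ± 0.13 and lipid synthesis genes at 5.62 ± 0.22, the latter with Scd1 at 1409 and 936 TPM and Fasn at 1153 and 1202 TPM.

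Levels of marker lists rest on different genes and do not measure amounts of cells. Monocyte and interstitial macrophage genes had a median of 5.33 ± 0.05 and alveolar macrophage genes 4.85 ± 0.10, with Ear2 at 294 and 258 TPM and Chil3 at 249 and 191 TPM. B cell genes had a median of 3.10 ± 0.12, while T cell genes (1.69 ± 0.18), natural killer cell genes (1.73 ± 0.06) and dendritic cell genes (1.65 ± 0.34) were lower. Mast cell and basophil genes were the lowest of the blood and immune cell lists named here, at 0.44 ± 0.12. Platelet genes had a median of 3.96 ± 0.20, neutrophil genes 3.55 ± 0.67 and plasma cell genes 3.18 ± 0.65. Erythroid genes had the highest median of the 41 lists, 10.50 ± 0.77, over the 7 of 9 members measured. Neuroendocrine genes stood at 1.16 ± 0.36, and interferon-stimulated genes at 3.03 ± 0.28. Cell cycle genes had a median of 1.42 ± 0.54, with 5 of 10 members above 1 TPM in both libraries. Immediate early genes stood at 5.37 ± 0.16, heat shock genes at 5.09 ± 1.22 and circadian clock genes at 4.09 ± 0.39. Y-linked genes had a median of 2.38 ± 0.50, and Xist, the RNA of X inactivation, a level of 0.03 ± 0.02.

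Markers of neighbouring organs ranged from undetected to high. Cardiac muscle genes, which mouse pulmonary veins also express, had a median of 5.95 ± 1.08 with 11 of 12 members above 1 TPM in both libraries. Thymus genes had a median of 0.01 ± 0.02, tracheal cartilage genes 0.20 ± 0.19, thyroid genes 0.88 ± 0.06 and liver genes 1.69 ± 0.37. Adipose tissue genes had a median of 4.11 ± 0.91. Oesophageal epithelium (4.56 ± 6.24), skeletal muscle (3.46 ± 4.12) and basal airway epithelium (3.05 ± 3.53) had SDs larger than their medians. In all, 18 of the 41 lists lay above the 95th percentile of random lists.

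**Figure D1:**
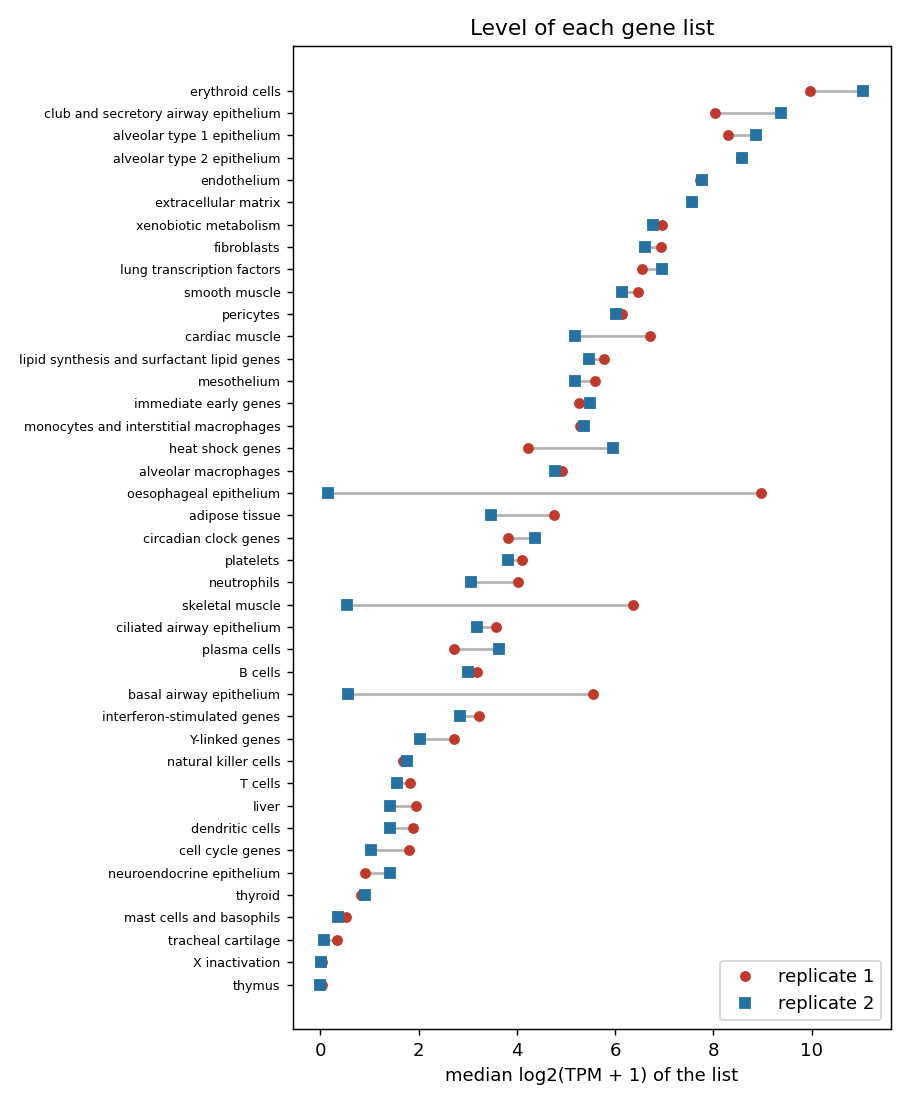
Median log2(TPM + 1) of each of the 41 gene lists in replicate 1 (circles) and replicate 2 (squares), joined by a grey line. Alveolar type 2, endothelial and extracellular matrix lists lie close together in the libraries, whereas oesophageal epithelium, skeletal muscle and basal airway epithelium lie far apart.

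The libraries resembled each other across most genes and differed strongly in a minority. Over the 15136 genes at 1 TPM or more in either library, Pearson's r of log2(TPM + 1) was 0.941 and Spearman's rho was 0.943. These are correlations across genes, which are not independent replicates. The robust SD of log2 expression per library was 0.32 over 17327 genes, and edgeR's common dispersion gave a biological coefficient of variation of 0.385. Of the 14708 genes with a mean count of at least 50, 93.3% were within 2-fold of each other. The other 982 genes comprised 655 higher in replicate 1 and 327 higher in replicate 2. Counting noise alone gave 0.15 such genes on average in 20 simulated pairs, which leaves out any variation between tissue samples. A simulated pair with a coefficient of variation of 0.2, below the measured one, had 285 of 14514 unchanged genes 2-fold apart. The share of those genes higher in replicate 1 was 66.7%; it was 77.7% when scaled by library size and 80.9% on log2(TPM + 0.1), where the median log2 ratio of genes with a mean count of at least 10 lay at -0.15 and -0.22, against -0.02 with TMM scaling.

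**Figure D2:**
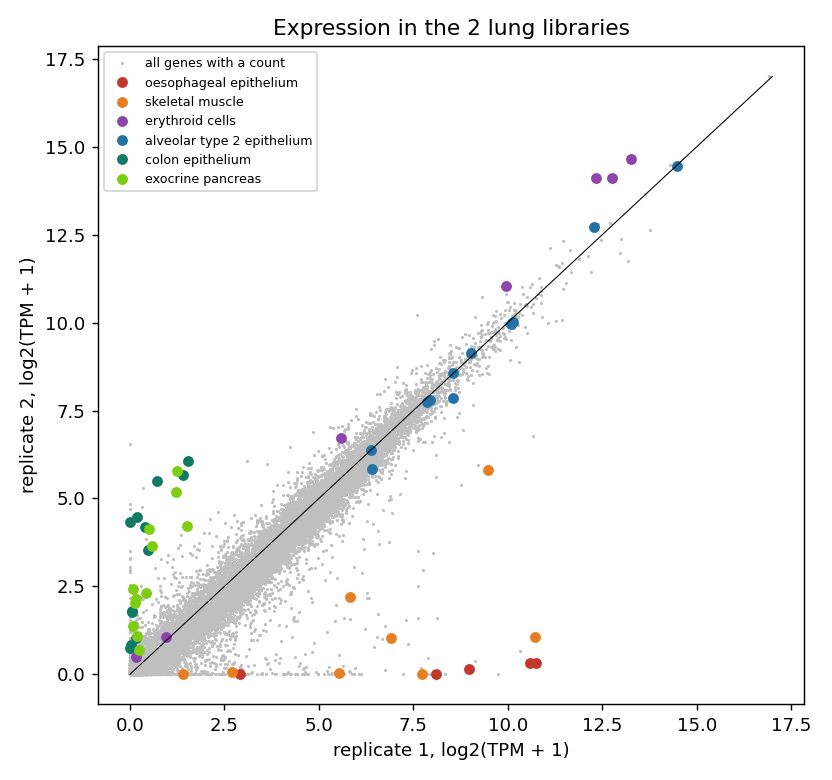
Each point is a gene at its log2(TPM + 1) in replicate 1 (horizontal) and replicate 2 (vertical), and the line marks equal levels. Oesophageal and skeletal muscle genes lie below the line (Krt4 at 1536 against 0.24 TPM), erythroid, colon and pancreas genes mostly above it, and alveolar type 2 genes along it.

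Genes of stratified squamous epithelium and of skeletal muscle made up the 12 largest differences towards replicate 1. Krt13, a keratin of oral and oesophageal lining (chromosome 11, 100117327 to 100121566), had 90014 counts in replicate 1 and 12 in replicate 2, a 6253-fold difference (95% exact interval 3579 to 12101). Krt4, its pairing partner (chromosome 15, 101918535 to 101924735), had 106639 against 16 counts, a 5556-fold difference (3421 to 9720). Sprr3 had 18419 against 4 counts and Cnfn 17931 against 8. The late cornified envelope genes Lce3a, Lce3b and Lce3c, together with Crct1 and Mt4, had no counts in replicate 2. A count of 0 allows up to 3, so Lce3c was at least 1148-fold and Mt4 at least 1573-fold higher in replicate 1. The myosin gene Myh8 (at least 2180-fold), the troponin gene Tnnc2 (at least 1034-fold) and Myh1 (9154 against 4 counts) completed these 12. Intervals and bounds cover counting error only. The bounds hold the replicate 1 count fixed and lie above the exact 95% lower limits. Those limits were 933 for Lce3c, 1279 for Mt4, 1772 for Myh8 and 840 for Tnnc2.

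All 5 oesophageal markers and all 8 skeletal muscle markers were 2-fold or more higher in replicate 1, with median log2 ratios of replicate 2 over replicate 1 of -11.37 and -6.94. With members lacking counts in replicate 2 set at their bounds, these medians were -11.37 and -6.58. Krtdap and Krt6a had no counts in replicate 2. Acta1 had 74437 against 47 counts and Ckm 30995 against 2326. Of the basal airway epithelium markers, 4 of 5 were also 2-fold or more higher in replicate 1. Krt5 was 105-fold higher (79.6 to 143) and Krt14 97.3-fold higher (63.5 to 158). Keratins of this list are also made by squamous epithelium of other organs. Tracheal cartilage genes had a median log2 ratio of -2.73 over 3 measured members, with Acan at 96 against 8 counts; on log2(TPM + 0.1) the list was at -1.26, inside the range of random lists. Cardiac muscle genes had a median of -0.52, with Myl3 at 5089 against 260 counts and Myl7 at 2478 against 2311.

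Haemoglobin genes were higher in replicate 2. The erythroid list had a median log2 ratio of 1.53, and 6 of 7 members were 2-fold or more higher. Hba-a1 was 3.96-fold higher (3.92 to 4.00), Hba-a2 3.08-fold, Hbb-bs 2.75-fold higher, and Alas2, the erythroid enzyme of haem synthesis, 2.88-fold. The alpha-globin copies share sequence, so reads can be divided between them in more than 1 way. Plasma cell genes had a median of 1.45, with Jchain (294 against 788 counts) and Igha (1432 against 3257 counts) among the 3 members 2-fold or more higher. Neuroendocrine genes had a median of 1.31, with Calca at 15 against 41 counts, while Syp, the member of highest TPM, had 375 against 275. The neuroendocrine list had too few members for a minimum of 50 counts. The colon gene Muc2 (65.5-fold) and the pancreas gene Ctrb1 (47.1-fold) were higher in the same library as these lists. The adipose list had a median of 1.11 but went both ways: Adipoq (669 against 2024 counts), Cidec, Plin1 and Retn were 2-fold or more higher in replicate 2, while the brown fat genes Ucp1 (8196 against 98 counts) and Cidea (6.59-fold) were higher in replicate 1. Retn was under 2-fold when scaled by library size. The median level of this list was lower in replicate 2 (3.47 against 4.75), opposite to its median ratio.

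The 12 largest differences towards replicate 2 included genes of intestinal and pancreatic epithelium at low level. Lypd8 had 23 counts in replicate 1 and 1475 in replicate 2, a 76.9-fold difference (51.1 to 122). The intestinal mucin gene Muc2 had 48 against 2619 counts, a 65.5-fold difference (49.2 to 89.0), and Guca2a had 2 against 290. The zymogen granule gene Sycn was at least 123-fold and the chymotrypsin gene Ctrc at least 46.0-fold higher, each without counts in replicate 1, as was Tff3 with 190 counts in replicate 2. Muc3 (2 against 229 counts) and Prss32 (1 against 226) belonged to the same 12. The remainder were Eno1b (15 against 2072 counts), Gm28037, Gm6166 and Gm13316.

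Regulatory gene groups also differed between the libraries. Of 15 circadian clock genes, 4 were 2-fold or more higher in replicate 2 and 2 were 2-fold or more higher in replicate 1, with a median of 0.62. Dbp (1973 against 6847 counts) and Per2 (1238 against 3874) were higher in replicate 2, and Arntl (1174 against 357) and Npas2 (1182 against 450) in replicate 1. Immediate early genes had a median of 0.69, with 13 of 14 members higher in replicate 2, or 12 on log2(TPM + 0.1). Heat shock genes had a median of 0.43, in which Hspa1a was 6.35-fold (5.96 to 6.77) and Hspa1b 5.70-fold (5.40 to 6.01) higher in replicate 2; on log2(TPM + 0.1) the list was at 0.15, inside the range of random lists. All 16 lung transcription factors were higher in replicate 2, with a median of 0.52 and Klf2 2.90-fold higher; on log2(TPM + 0.1), 14 were higher, and Sox2 and Foxp2 were not. Mesothelial genes had a median ratio of 0.59, although their median level was lower in replicate 2 (5.19 against 5.58), and natural killer cell genes had 0.49. Towards replicate 1, neutrophil genes had a median of -0.99, with Retnlg at 569 against 128 counts and S100a9 at 291 against 76. Liver genes had a median of -1.10, Y-linked genes -0.68, cell cycle genes -0.62, smooth muscle genes -0.36, lipid synthesis genes -0.17 and xenobiotic metabolism genes -0.052. Matched random lists ranged from -0.042 to 0.340 for lipid synthesis and from -0.048 to 0.347 for xenobiotic metabolism. These ranges were mostly positive, so both medians were low relative to genes of like expression while small in size. With members of a mean count of at least 50, the liver, cell cycle (-0.59) and xenobiotic metabolism lists lay inside the range of random lists.

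A further set of lists lay inside the range of random lists matched on expression. These were alveolar type 2 (0.16), alveolar type 1 (0.000579), club and secretory (0.37), ciliated (-0.13), endothelium (0.08), fibroblasts (0.21), pericytes (0.06) and extracellular matrix (0.18). For alveolar type 1 the random range was -0.02 to 0.42, so its median lay near the lower end. The same held for alveolar macrophages (0.05), monocytes (0.17), dendritic cells (0.05), B cells (-0.41), T cells (-0.33), mast cells (0.20), platelets (-0.22), interferon-stimulated genes (-0.21) and thyroid (0.56). On log2(TPM + 0.1), 10 of these medians turned negative: alveolar type 1 and 2, endothelium, fibroblasts, pericytes, extracellular matrix, alveolar macrophages, monocytes, dendritic cells and mast cells. In total, 22 of 39 lists lay outside the central 95% of 10000 random lists, 12 towards replicate 1 and 10 towards replicate 2. Random lists hold unrelated genes, whereas members of a marker list can vary together and some lists share Abca3, Lpcat1 or Cyp2f2, so this range is a description and not a chance level. Thymus and X inactivation had fewer than 3 members with enough counts.

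**Figure D3:**
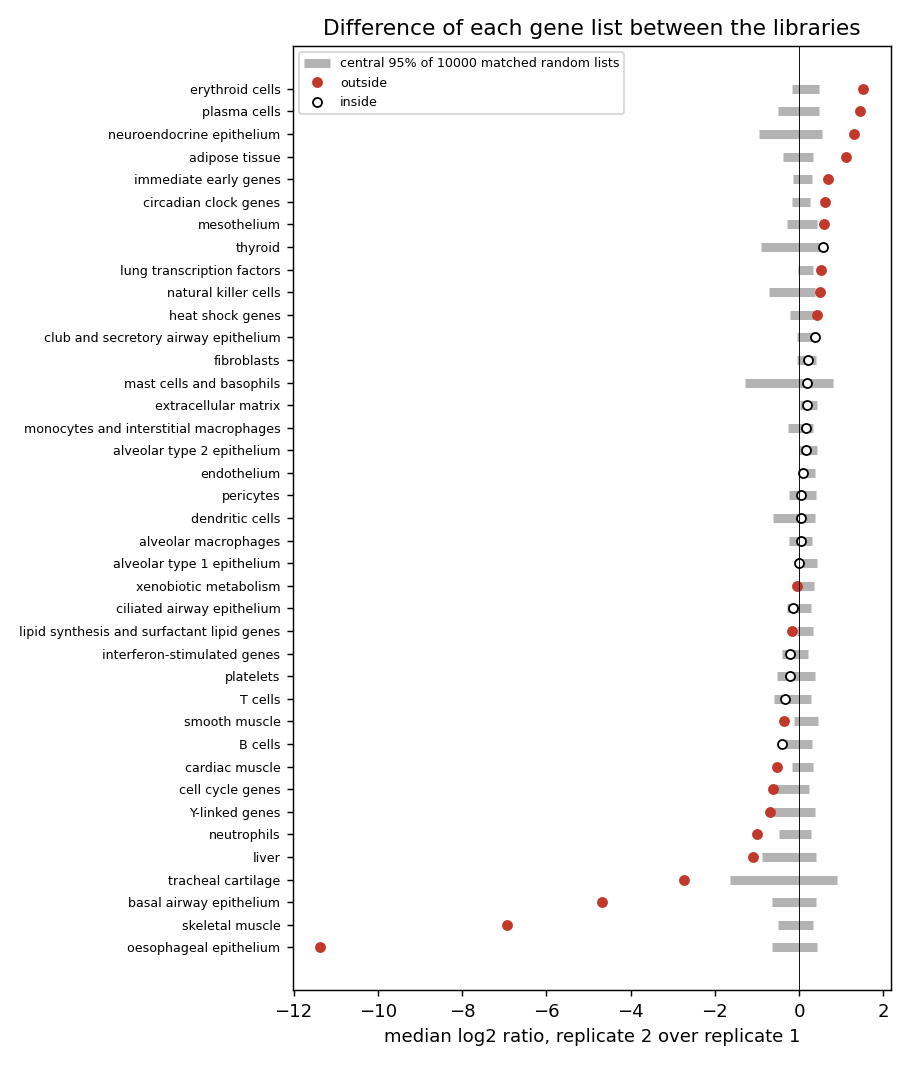
Median log2 ratio of replicate 2 over replicate 1 for 39 gene lists (points), with the central 95% of 10000 random lists matched on expression (grey bars). Filled points, 22 in all, lie outside the bars.

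Of 7372 multi-transcript genes at 5 TPM or more in both libraries, 6329 had the same main transcript in both (85.9%, 95% Wilson interval 85.0 to 86.6). The interval treats genes as independent and does not measure how this share would vary between other pairs of libraries. For Ager, the receptor of advanced glycation end products, Ager-201 held 67.7% ± 1.41 of the gene's TPM and Ager-209 held 27.7% ± 0.318. Pkm-201 held 81.6% ± 5.76 of Pkm, Ace-201 held 71.2% ± 3.37 of the angiotensin-converting enzyme gene and Nkx2-1-202 held 96.2% ± 1.08 of Nkx2-1. The main transcript of Sftpb was Sftpb-202 at 79.8% ± 1.87, which the later annotation lists as subject to nonsense-mediated decay. Ednrb-202 held 65.9% ± 0.424 and Cd44-203 held 54.5% ± 5.57. The leading transcript differed between the libraries for Tpm1, where a transcript of 1208 nt held 54.0% in replicate 1 and 28.2% in replicate 2, and one of 1607 nt held 19.6% and 35.1%. In TPM the former stood at 172 and 44.1 and the latter at 62.6 and 54.9. Skeletal muscle genes were also high in replicate 1, and whether this shift belongs to lung cells was not tested. In Vegfa, Vegfa-203 held 35.8% and 19.3%, Vegfa-201 held 18.3% and 27.3%, and Vegfa-207 held 9.28% and 25.7%. In Fgfr2, Fgfr2-221, annotated as a retained intron, held 32.2% and 23.6%, and Fgfr2-211 held 19.6% and 25.3%. Fn1-203 held 24.2% ± 8.78 and Ptprc-213 held 41.7% ± 12.3. Scgb1a1, Sftpc, Eln, Myl6 and Epcam had 1 annotated transcript each.

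Synthetic spike-in RNAs took 1.44% of counts in replicate 1 and 1.03% in replicate 2. Of 58 spike-ins with a mean count of at least 10, 56 were lower in replicate 2 after scaling by library size, with a median log2 ratio of -0.53.

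Junctions and contigs were listed once for the series, on mm9, without a gene annotation of that build used here. Of 447240 splice junctions, 154584 had a reproducibility value of at most 0.1, and these held 98.2% of the 35330315 junction reads. Their median intron length was 1274 nt. The most used junction (chromosome 19, 9159866 to 9162336, minus strand) had 445592 reads. Of 795937 contigs, 415018 passed the same value and covered 244 Mb, with a median length of 397 nt; 209256 lay on the plus strand and 205762 on the minus strand.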

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

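Junctions were examined for the items here after the list had been seen, and none was planned. The junction list entered no comparison between the libraries. The mitochondrial chromosome, whose genes have no introns, carried 180 listed junctions on mm9 with 406 reads, or 0.00115% of junction reads. Of these junctions, 131 had 1 read and 6 had a reproducibility value of at most 0.1.

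Junctions joining the start of a heavily used intron to the end of another were found in pairs on chromosomes 11 and 7 of mm9. On chromosome 11, the junction from 32184129 to 32197079 had 326619 reads, against 332469 and 326546 for the 134 nt introns at its ends. The junction from 32183802 to 32196740 had 52006 reads, against 52026 and 52062 for introns of 122 nt. On chromosome 7, the junction from 110961299 to 110975961 had 41219 reads, against 41162 and 95130. The junction from 110962176 to 110976297 had 25661 reads, against 29546 and 25665. Each joining junction thus had nearly the same number of reads as an intron at its ends. Splicing between genes does not require such equality. The list gives no placements of single reads, so neither splicing between genes nor reads placed across similar sequences was tested.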

How the results depend on the processing

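With either replicate left out, genes detected ranged from 14138 to 14853, the share of TPM in the 10 highest genes from 23.4% to 27.3%, the mitochondrial share from 1.53% to 3.18%, and lists above the 95th percentile from 19 to 20. Ranked by expected count, which takes a different set of genes, the 10 highest held 8.92% of counts. The mitochondrial share was 1.21% of expected counts, against 2.35% of TPM. The correlation was 0.904 with a pseudocount of 0.1 and 0.980 with no filter. The replicate SD was 0.28 at a mean count of at least 100 and 0.33 on log2(TPM + 0.1). The coefficient of variation was 0.394 with no filter on counts above 0 and 0.385 with DESeq2 size factors. The 2-fold count was 1746 at a minimum of 10 and 538 at a minimum of 200, where more and fewer genes enter. Main transcripts matched in 86.8% of genes at 20 TPM or more and 94.0% of genes whose main transcript held at least 50%. The spike-in share was 1.89% of TPM, and 251083 contigs passed a reproducibility value of 0.01. Where no reason is given, the cause was not tested. The other alternatives left counts within 1.5 times the reported value. Of the 41 list levels, 20 moved by more than their SD on FPKM and 13 with a pseudocount of 0.1. Of the 982 genes called 2-fold, 971 remained so with DESeq2 scaling, 889 with library size scaling and 825 on log2(TPM + 0.1), where 156 came under 2-fold and 1, Foxn4, changed sign. No list outside the random range changed direction under the alternatives run; on log2(TPM + 0.1), 2 such lists came inside the range and 10 lists inside it changed sign. At a minimum of 50, 3 lists came inside and 3 had too few members. No paired analysis was possible because there is 1 group. Depth limits genes under about 10 counts.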

Other observations

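Lists of other organs and all tests here were chosen after the patterns were seen, except the X chromosome comparison; of the keratin comparison, Krt4 and Krt13 had been seen and Krt1 and Krt10 had not. White adipose genes were higher in replicate 2. Cfd, which encodes adipsin, had 4947 counts in replicate 1 and 29964 in replicate 2, and 5 of 7 white adipose genes were 2-fold or more higher there (median log2 ratio 1.51). Brown adipose genes went the other way, with a median of -2.67 and 5 of 6 members 2-fold or more higher in replicate 1. All 7 white and 4 of 6 brown adipose genes were above 1 TPM in both libraries, and 5 and 2 of them, respectively, are also in the fixed adipose list.

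Of 10 kidney genes, the 5 with a mean count of at least 10 had a median of 0.80. Klk1 had 46 against 440 counts, Slc34a1 20 against 98, Umod 19 against 29 and Aqp2 43 against 52. Among these genes only Pvalb, also a skeletal muscle marker, was lower in replicate 2, at 147 against 1. For testis genes the median was 1.29 over 3 members, with Prm2 at 11 against 25. Small intestine genes had a median of 0.04, brain genes -0.28 and adrenal cortex genes 0.25. The small intestine median was that of Anpep (6309 against 5404 counts), and other members went both ways, with Alpi at 1 against 29 and Apoa4 at 15 against 5. Gastric gland and mammary or salivary genes had too few members with counts, 2 and 1. Squamous genes of the upper digestive tract had a median of -8.69 over 7 members and epidermal genes -4.40 over 4, or -4.04 with the member lacking counts at its bound. The epidermal members split. Krt10 had 38 against 40 counts and Krt1 19 against 9, whereas Dsc1 had 595 against 0 and Lor 11709 against 8. Of the kidney genes 1 was above 1 TPM in both libraries, of the small intestine genes 1, gastric 1, mammary or salivary 1, brain 5, squamous 2, and of the testis, adrenal and epidermal genes 0. The fixed lists share 1 kidney gene and 3 squamous genes.

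Squamous and skeletal muscle genes were high in replicate 1. A change of airway basal cells into squamous cells would leave skeletal muscle genes in place, but that list had a median log2 ratio of -6.94. Such a change would thus not account for the muscle genes. It stays open for the squamous genes, because the muscle genes were part of the pattern and do not test it there. Epidermis as the whole source is argued against by Krt1 and Krt10, whose summed TPM over that of Krt4 and Krt13 was -11.99 on the log2 scale, although the epidermal gene Lor had 207 TPM. RNA of upper digestive tract or neck tissue, from dissection or the library, stays open: 100% of the 13 oesophageal and skeletal muscle markers were 2-fold or more higher in replicate 1, with Krt13 at 1725 TPM and Acta1 at 1684 TPM, but these genes showed the pattern and do not test it. In these data, the change of basal cells was the only biological explanation considered, and for the squamous genes it was not tested.

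Colon and exocrine pancreas genes were high in replicate 2. The pancreas and colon lists had median log2 ratios of 4.57 and 5.36, so RNA of either organ alone would not account for both. Genes of both organs had been seen before these lists were written, so this outcome was known in advance. Reads of other mouse organs in equal measure are argued against by the liver list, at -1.10. Among the added lists, testis was at 1.29 over 3 members, adrenal cortex at 0.25, small intestine at 0.04 and brain at -0.28. Kidney was at 0.80 with the muscle marker Pvalb included, its only member lower in replicate 2 at a mean count of at least 10. RNA or reads of both organs in that library stay open. At a mean count of at least 10, 24 of 24 members were 2-fold or more higher, led by Phgr1 (65.6 TPM) and Ctrb1 (54.2 TPM). Many members were chosen because they had been seen, so the count does not test this explanation. Of these, 2 colon and 3 pancreas genes were above 1 TPM in both libraries, the step at which they entered stays open, and no biological explanation was tested.

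Xist, which is transcribed from the inactive X chromosome of females, had 17 and 8 counts although the labels name both sexes, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty all exceeded 1 TPM in both libraries. Assignment of its reads to the antisense gene Tsix is argued against, since Tsix had 102 expected counts over both libraries. Low depth over the X chromosome is argued against, since the lower X share of counts was 0.633 of the X share of detected genes. Little or no female RNA in the libraries stays open, since Xist at 0.03 TPM at most is the pattern itself and does not test it. No female reference library was used here, and a gap in the quantified Xist annotation was not tested.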
